A study of Homo sapiens with 8 samples.

How the data were processed

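The series holds 8 chromatin immunoprecipitation (ChIP) sequencing libraries of neural progenitor cells made from H9, an established human embryonic stem cell line. Before differentiation the stem cells had received a control lentivirus or a lentivirus with either of 2 hairpins against KDM2A, named sh1 and sh4. KDM2A removes dimethylation from lysine 36 of histone H3 (H3K36me2) and binds unmethylated CpG-rich DNA through a zinc finger. H3K36me2 was precipitated from the control, sh1 and sh4 cells, and KDM2A itself from the control cells. Each of these 4 libraries has a deposited peak list, and the 4 matching inputs were not analysed here as libraries of their own. Every group holds 1 library, so no value below has a spread between replicates and no test between groups was possible.

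The authors' processing notes name Bowtie 1.1.2, MACS2 and SICER and the builds hg38 and GRCh38, with no role given to any of them. In the deposited H3K36me2 lists the regions lay on a grid of 200 bp, starts counted from 0, and the smallest gap between neighbouring regions was 800 bp. The deposited fold enrichment is a linear ratio of immunoprecipitate (IP) to background per region. The p-value and FDR of each region come from the authors' peak caller, and every deposited FDR lay under 1e-05. The deposited score of a region equals 100 times the log2 of its fold, capped at 1000. In the deposited KDM2A list the fold enrichment is a ratio of the IP to local background, and the authors' pileup is a signal, the height of stacked fragments at the peak, from 5 to 235. The authors' p-values for KDM2A peaks reached 0.0495 and their FDR reached 0.869, so that list is broad and no FDR limit had been applied to it.

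The lists hold no library totals. For the H3K36me2 lists, the IP and input read counts of each region were recovered from its fold and p-value, which together fix both numbers under a Poisson model. In each library 100% of the recovered IP counts lay within 0.001 of a whole number and 100% of the input counts within 0.01. The depth of the KDM2A library is unknown beyond its pileup.

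Gene positions came from a RefSeq annotation of GRCh38.p14 that gives both ends of each gene but no strand. The windows planned around transcription start sites were therefore placed around both ends of every protein-coding gene, 2 kb to each side. As a check chosen later, 556 genes were used whose own annotated divergent transcript, within 2000 bp, shows which end is the start. Genes of unplaced or alternate sequences, which the annotation lists under a chromosome's name with other coordinates, were left out (679 genes, 153 of them protein-coding). This left 19817 protein-coding genes on chromosomes 1 to 22 and X. Peaks on other sequences were counted once and not used further.

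KDM2A peaks were placed by their midpoint. Their share near gene ends was set beside 100 random placements on the same chromosome, within windows of 100 kb that held at least 1 KDM2A peak (2908 Mb in all). A gene counted as KDM2A-bound if a peak overlapped either end window. For H3K36me2, the number of regions, covered length and width were taken per library. The length shared by 2 libraries was set beside 100 draws in which the regions of 1 library were moved along the chromosome by 0.1 to 1 Mb. Each library was taken in turn as the reference, because both hairpins share 1 control. Coverage of a gene body is the percent of its length inside H3K36me2 regions. Windows of 1 Mb were classed by their number of protein-coding genes, a division made after the values had been seen.

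There were 17 gene lists, and all their members were found in the annotation. They were neural progenitor markers, neurogenesis and neuron differentiation, axon guidance and synapse, MAPK signalling, growth factor receptors and ligands, and Wnt, Notch and Hedgehog signalling. Further lists were pluripotency, mesoderm and endoderm, neural crest, astrocyte and oligodendrocyte, H3K36 methylation enzymes and readers, Polycomb group, HOX genes, ribosomal proteins and cell cycle. The last lists held genes of blood, liver and muscle, and olfactory receptors, neither expected in neural cells. A list's value was ranked as a percentile among 10000 random lists of the same size, matched on deciles of gene length and, for H3K36me2, of control coverage. Such a percentile describes these libraries only and carries no variation between cultures.

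The genes named were set by rule. KDM2A and KDM2B were always taken. For KDM2A these were the 10 genes with the highest fold at a gene end and up to 4 per list. For H3K36me2 these were, among genes of at least 5 kb, the 10 largest falls and 10 largest gains in coverage. They were ranked by the smaller of the changes in the hairpins, with up to 4 genes per list. The widest regions found in the control alone, or in both hairpins and not in the control, were also taken. Values of some genes this rule names are not reported here. Groups, most comparisons, lists, this rule and most of the other settings tried were fixed before the data were examined. The comparison by gene density and the ratios of genes with any H3K36me2 in the body were not planned.

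Intervals of shares are Wilson 95% intervals, and those of ratios were formed from them or from the counts on a log scale. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. Intervals of covered length treat each region as 1 count. The alternatives tried were other windows, other peak limits, equal numbers of regions, joined regions and other definitions of overlap. Chosen after seeing the data were a limit of FDR under 0.05 for KDM2A peaks, the genes with a known start, and leaving out chromosome 1 beyond 140 Mb. An exact binomial test of IP against input counts per region, with a Bonferroni limit over the candidate regions, was also set after seeing the data.

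The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. Read counts were recovered exactly for 99.98% of 5000 simulated regions. Of 100 simulated lists of 40 genes with no shift, 5% fell outside percentiles 2.5 to 97.5, and a shift of 0.8 SD was found in 100% of them. The simulated gene values were continuous with independent noise, unlike peak overlap or coverage. These shares therefore test the calculation and do not give the error rate or power for the reported lists.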

Results

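The data were 4 lists of ChIP-seq peaks from neural progenitor cells derived from H9 human embryonic stem cells, 1 library per group. KDM2A was mapped in control cells, and H3K36me2 in control cells and in cells with the KDM2A hairpins sh1 or sh4. The control H3K36me2 list held 19691 regions, the sh1 list 19501 and the sh4 list 21493. The median region held 162 IP reads and 99 input reads in the control, 151 and 89 in sh1, and 156 and 92 in sh4. At those counts a typical region's fold had a counting interval of 1.25 to 2.09 in the control, 1.28 to 2.21 in sh1 and 1.29 to 2.19 in sh4. The KDM2A list held 504724 peaks with a median fold of 2.33 and a median pileup of 8, and 15820 of them (3.13%) had an FDR under 0.05. No replicates exist, so the spread between libraries of 1 group is unknown for every value.

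Where KDM2A lay relative to genes was the question of the KDM2A library, since the study describes binding at transcription start sites. KDM2A peaks gathered at the gene starts that could be placed. These belong to genes with an annotated divergent transcript and need not stand for all gene starts. The random placements were not matched on CpG content. Among 556 genes with a known start, 583 peaks lay within 2 kb of the start, 1.48 times the number under random placement (interval 1.36 to 1.61). At the other end of the same genes the ratio was 1.11 (1.01 to 1.22; 435 peaks). Within 500 bp the ratio was 2.48 at starts (2.19 to 2.81; 240 peaks) and 1.02 at the other ends (0.836 to 1.24; 99 peaks). Of the peaks with an FDR under 0.05, 26 lay within 2 kb of these starts, a ratio of 2.17 (1.48 to 3.18), and 10 at the other ends, a ratio of 0.782 (0.425 to 1.44).

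**Figure D1:**
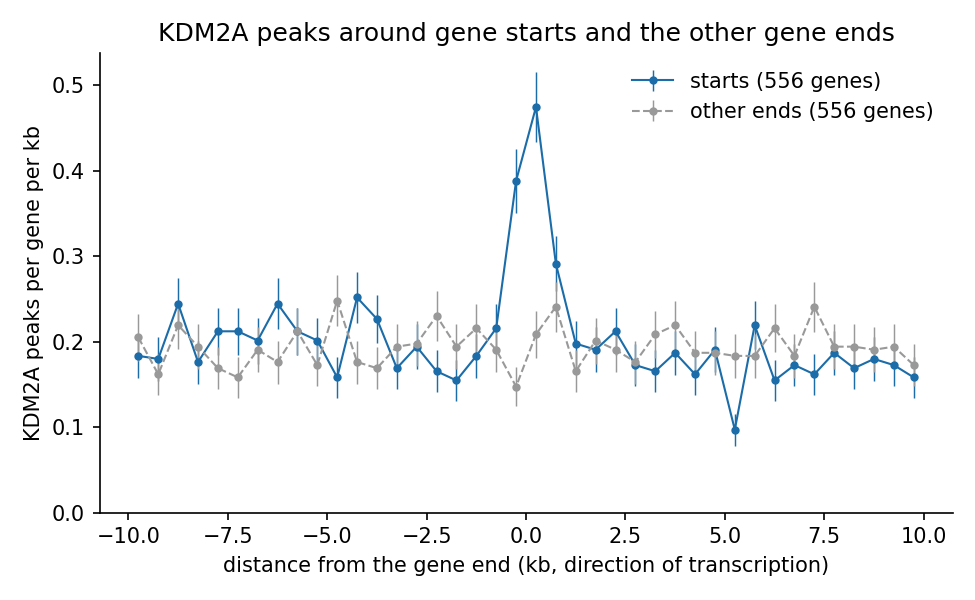
KDM2A peaks per gene per kb (vertical axis) by distance from the gene end in kb (horizontal axis), in bins of 500 bp, for the starts and the other ends of 556 genes in the 1 control library; bars are 1 Poisson standard error. The profile at starts peaks at 0.475 in the bin centred 250 bp into the gene, while at the other ends the highest bin, at 0.248, lies away from the end.

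Over both ends of all 19817 protein-coding genes, 6.40% of KDM2A peaks lay within 2 kb (6.33 to 6.47), against 4.93% under random placement, a ratio of 1.30 (1.29 to 1.31). Counted on the 200 bp grid, 6.66% of peaks lay at gene ends, 39.6% in gene bodies and 53.8% between genes. Most genes had a KDM2A peak at an end, namely 16654 (84.0%), and 1100 (5.55%) had a peak with an FDR under 0.05. The first of these counts therefore separates few genes.

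The KDM2A peaks with the highest folds at gene ends lay at genes of varied function. KHSRP, an RNA-binding splicing regulator (gene 8570, chromosome 19, 6413102 to 6424811), had a peak at 6411323 to 6411681 with a fold of 8.45 and FDR of 3.35e-18. AGMAT, which encodes agmatinase (gene 79814, chromosome 1, 15571699 to 15585051), had a fold of 6.76. OR7G2, an olfactory receptor on chromosome 19, had a fold of 6.48, and GCDH, which encodes the glutaryl-CoA dehydrogenase of lysine breakdown, one of 6.001. The fold was 5.99 at TRIM58 and at NRIP3, 5.85 at the pyruvate kinase gene PKM, 5.80 at HEBP2, 5.48 at the mitochondrial chaperone gene CLPB and 5.40 at ELMOD1. The KDM2A gene itself (gene 22992, chromosome 11, 67119263 to 67258082) had no peak at either end. Its paralogue KDM2B (gene 84678, chromosome 12, 121408461 to 121582279) had a peak with a fold of 2.58 and FDR of 0.324.

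The series names neurogenesis and neuron differentiation for KDM2A and MAPK signalling in its title. Of the 38 neurogenesis and neuron differentiation genes, 37 had a KDM2A peak at an end, against a median of 84.2% in random lists matched on gene length (percentile 99.4). Folds in the list included 3.79 at EOMES, 3.45 at ATOH1 and 3.42 at LHX6, all transcription factor genes of neuron formation, each with an FDR under 0.05. The list left the outer percentiles under each other setting tried. With that FDR limit it held 4 bound genes (percentile 88.6), with 1 kb windows it lay at percentile 95.4, and with the 10% of peaks of highest fold at 76.7. Of the 39 HOX genes, the body-axis transcription factors, 38 had a peak (percentile 99.8). HOX genes sit in clusters and share peaks, so they are not independent. HOXA3 had a fold of 4.06 and HOXB7 one of 3.68. Of 74 MAPK signalling genes, 59 had a peak (percentile 14.1) and 6 had one with an FDR under 0.05 (percentile 82.7), among them the p38 kinase gene MAPK14 with a fold of 3.98, RRAS2 with 3.56, MAP3K3 with 3.54 and MKNK1 with 3.48.

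Ribosomal protein genes had KDM2A peaks less often than matched lists, in 30 of 51 (percentile 0.000), and olfactory receptors in 298 of 389 (percentile 0.670). The other lists lay within percentiles 2.5 to 97.5. Axon guidance and synapse genes had a peak in 29 of 30 (percentile 97.45), with folds of 3.19 at the ephrin gene EFNB2 and 3.18 at the netrin gene NTN1, both with an FDR of 0.102, and 0 of the 30 had a peak with an FDR under 0.05 (percentile 12.7). Neural progenitor markers had a peak in 20 of 24, with 3.94 at OTX2 and 3.63 at SOX9. Growth factor genes had a peak in 26 of 29, with 3.95 at the neurotrophin gene BDNF, and Wnt, Notch and Hedgehog genes in 30 of 34, with 3.61 at WNT3A. The count was 19 of 22 for pluripotency (3.85 at ZSCAN10), 27 of 30 for mesoderm and endoderm (3.47 at TWIST1) and 14 of 16 for neural crest (3.11 at SOX10). It was 18 of 21 for astrocyte and oligodendrocyte genes (3.48 at ALDH1L1), 18 of 21 for H3K36 enzymes and readers (2.95 at SMYD2) and 27 of 30 for Polycomb genes (3.54 at YAF2 and at BCOR). It was 26 of 34 for the cell cycle (3.54 at E2F1) and 26 of 30 for blood, liver and muscle genes. Of the peaks given for these lists, those at EFNB2, NTN1, TWIST1, SOX10 and SMYD2 had an FDR above 0.05. With the FDR limit, 0 of the 17 lists lay outside percentiles 2.5 to 97.5. Lists with 0 bound genes under that limit still lay at percentiles 8.27 to 19.6, so a short list could not reach the low tail.

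How far the knockdown altered H3K36me2 was the question of the other libraries. H3K36me2 regions covered 101.8 Mb in the control, 94.3 Mb in sh1 and 112.1 Mb in sh4, with median widths of 4400, 4200 and 4400 bp. Covered length in sh1 was 0.926 times the control (0.908 to 0.945) and in sh4 1.102 times (1.08 to 1.12), so the hairpins lay on opposite sides of the control. The median fold was 1.59 in the control and 1.65 in each hairpin library, and 7.78% of control regions had a fold above 2, against 13.9% in sh1 and 14.6% in sh4. Called regions held 23.3, 22.5 and 21.6 input reads per kb in control, sh1 and sh4. The 10th percentile of their folds was 1.38, 1.41 and 1.41. A difference in the mark was therefore not separated from a difference in the calling limit. The direction for sh1 turned when only regions above the control's median fold were kept, with 1.24 for sh1 and 1.50 for sh4, and among regions that passed the exact binomial test, with 1.49 and 2.61. Without chromosome 1 beyond 140 Mb the ratio for sh4 was 0.986 (0.966 to 1.01).

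The excess of sh4 over the control in the full list came from chromosome 1 beyond 140 Mb. Covered length without this part was not computed for the fold limit or the binomial test. By number, 1308 regions outside this part passed the binomial test in control, 2094 in sh1 and 2970 in sh4. H3K36me2 regions covered 3.74 Mb there in the control, 3.13 Mb in sh1 and 15.5 Mb in sh4. The genes PTPRC, XCL1, FMO2 and ANGPTL1 lie in this part. PTPRC, the leukocyte common antigen gene (chromosome 1, 198638713 to 198757476), was covered over 2.19% of its length in the control, 6.40% in sh1 and 51.6% in sh4. In 118 windows of 20 Mb elsewhere with at least 0.3 Mb covered in the control, sh4 covered 0.275 to 1.82 times the length of the control.

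**Figure D2:**
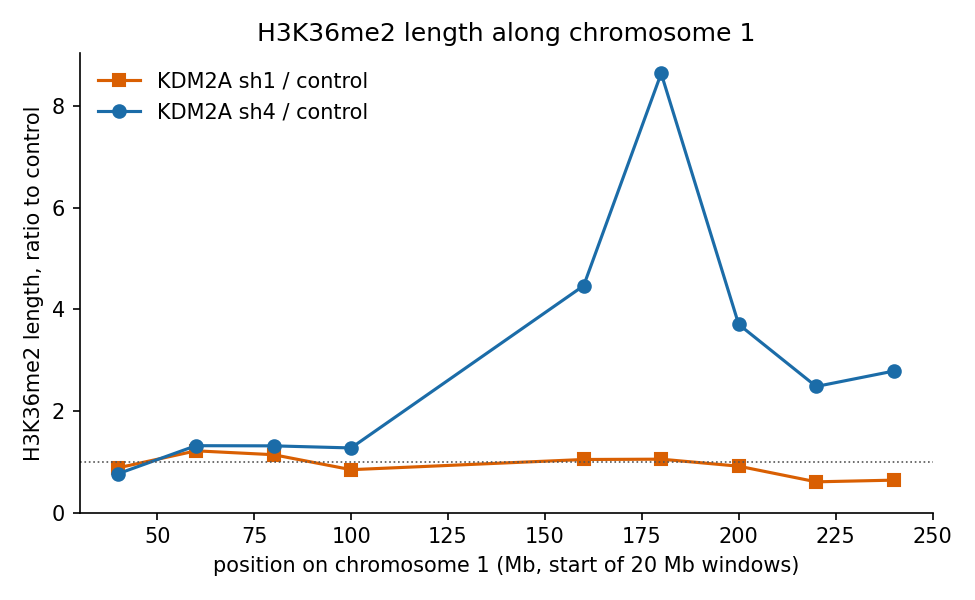
Length in H3K36me2 regions relative to the control (vertical axis, ratio) along chromosome 1 (horizontal axis, window start in Mb), for sh1 (squares) and sh4 (circles), 1 library each, in windows of 20 Mb with at least 0.3 Mb covered in the control; lines join the windows shown. From 160 Mb on, sh4 lies between 2.48 and 8.65 times the control and sh1 between 0.606 and 1.052.

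The regions of the 3 libraries seldom coincided. The control and sh1 shared 9.84 Mb, 9.67% of the control's length and 1.81 times the length shared after moving the regions by up to 1 Mb. The control and sh4 shared 8.83 Mb (8.68% of the control; 1.51 times), and sh1 and sh4 shared 10.7 Mb (11.3% of sh1; 1.76 times). All 3 libraries shared 1.38 Mb. Of the control's length 83.0% was found in the control alone, against 79.7% of sh1 in sh1 alone and 83.8% of sh4 in sh4 alone. The products of the single shares were 82.5%, 79.4% and 83.3%, each slightly below the observed share. Of the control's length 90.3% was missing from sh1 and 91.3% from sh4. This leaves little room between product and observed share, so the comparison is a weak check of whether misses were independent. The widest control regions absent from both hairpins lay in SH3BP5 (chromosome 3, 15305601 to 15331600, fold 1.22), FARS2 (chromosome 6, 5635601 to 5660600, fold 1.19) and RAD51B (chromosome 14, 68553401 to 68577800, fold 1.25). The widest stretches shared by both hairpins and absent from the control lay on chromosome 19 at 27345801 to 27372600, 1832720 bp from the nearest protein-coding gene, and on chromosome 1 at 168495601 to 168515400, 25368 bp from XCL2.

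**Figure D3:**
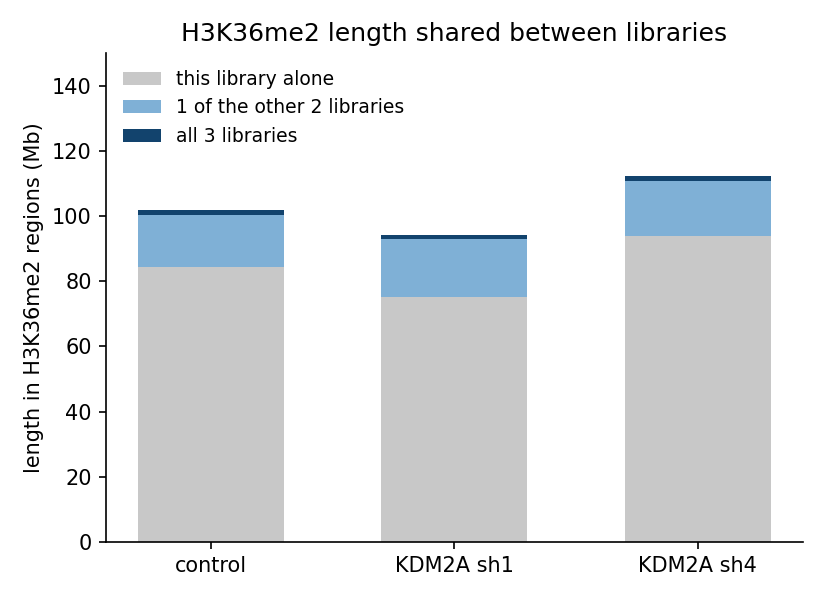
Length in H3K36me2 regions (vertical axis, Mb) in the control, sh1 and sh4 libraries (1 bar each), split into length found in that library alone, shared with 1 of the other libraries, and shared by all 3. Length found in 1 library alone makes up 79.7% to 83.8% of each bar.

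Both hairpin libraries held fewer H3K36me2 regions than the control in gene-rich sequence and more in gene-poor sequence. Windows of 1 Mb with 10 or more protein-coding genes held 2548 regions in the control, 1661 in sh1 (0.652 times, 0.613 to 0.693) and 1630 in sh4 (0.640 times, 0.601 to 0.681). Windows with fewer than 5 genes held 11130, 12335 and 14255. Relative to gene-poor windows, the gene-rich count was 0.588 times the control in sh1 (0.550 to 0.629) and 0.499 times in sh4 (0.467 to 0.534). This relative value stayed between 0.485 and 0.591 under every alternative tried. The count itself did not, since among regions that passed the binomial test it was 0.914 times the control in sh1 (0.712 to 1.17) and 1.41 times in sh4 (1.12 to 1.76). The classes of gene density were chosen after the values had been seen.

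**Figure D4:**
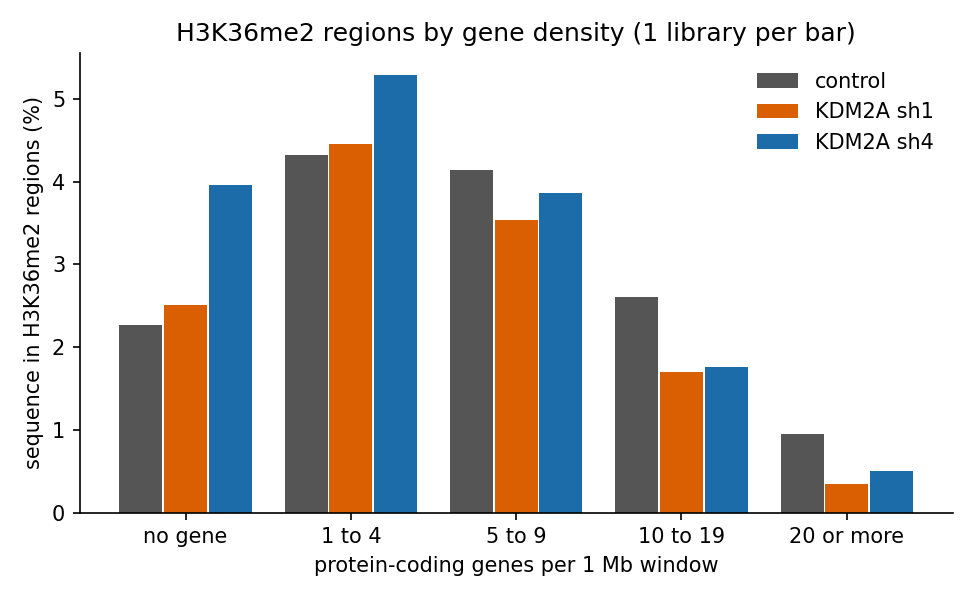
Percent of sequence inside H3K36me2 regions (vertical axis) in 1 Mb windows grouped by their number of protein-coding genes (horizontal axis), 1 bar per library with no replicates. In windows with 20 or more genes the control covers 0.947%, sh1 0.351% and sh4 0.497%, and in windows without a gene the control lies lowest, with 2.26%, 2.51% and 3.96%.

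Gene ends held little H3K36me2 in each library. The 2 kb around gene ends made up 4.92% of the genome windows used, and 2.40% of the control's H3K36me2 length, 1.72% of sh1 and 1.57% of sh4. Gene bodies made up 40.5% of those windows and 43.3%, 40.8% and 39.1% of the length. At the 556 known starts, 12 genes had a region at the start in the control, 9 in sh1 and 9 in sh4.

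Over gene bodies, 3973 of 19817 genes (20.0%) had any H3K36me2 in the control, 3207 (16.2%) in sh1 and 3061 (15.4%) in sh4. The ratios to the control were 0.807 (0.771 to 0.846) and 0.770 (0.735 to 0.808), and with regions above the control's median fold 0.961 (0.908 to 1.02) and 0.938 (0.886 to 0.993). Coverage was lower than the control in both hairpins for 2492 genes and higher in both for 929. For comparison, coverage was highest in sh1 alone for 1556 genes and in sh4 alone for 1737, and lowest in sh1 alone for 942 and in sh4 alone for 1040.

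Genes fully or largely covered in the control and covered over 0% in both hairpins were ZNF691, a zinc finger gene (gene 51058, chromosome 1, 42846613 to 42852477), at 100%, and the GDP-fucose transporter gene SLC35C1 (gene 55343, chromosome 11, 45804079 to 45813016) at 99.8%. They also were FAM50B at 93.8%, C1QTNF9B at 92.2%, KLHL38 at 91.9%, TBATA at 91.7%, MAGEB10 at 86.6%, the matrix metalloproteinase gene MMP7 at 81.0%, the photoreceptor retinoid-binding gene RBP3 at 78.6% and the neuronal gene TAGLN3 at 76.7%. Genes at 0% in the control and covered in both hairpins included 3 other metalloproteinase genes of the MMP7 cluster on chromosome 11. They were MMP3 (35.9% in sh1, 35.9% in sh4), MMP1 (22.8%, 60.2%) and MMP20 (22.7%, 30.9%). The others were XCL1 (54.9%, 100%), FMO2 (41.3%, 36.9%), SLC35G1 (32.8%, 40.4%), the histidine decarboxylase gene HDC (32.8%, 28.0%), ANGPTL1 (24.1%, 76.5%), CTXN3 (24.3%, 21.3%) and the angiotensin receptor gene AGTR1 (22.2%, 24.4%). Each of these values is a called or uncalled region of 1 library, and 83.0% of the control's length was found in the control alone.

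Among MAPK signalling genes, the pathway in the study's title, coverage was lower in both hairpins for 17 of 74 and higher in both for 9. Mean coverage was 3.21% in the control, 1.64% in sh1 and 2.16% in sh4, and the differences lay within those of matched random lists (percentiles 15.3 and 33.8). SPRY4, an inhibitor of receptor tyrosine kinase signalling (chromosome 5, 142310430 to 142325021), was covered over 76.6% in the control and 0% in both hairpins. The control values, with 0% in both hairpins, were 16.4% for MAPKAPK3, 13.3% for ELK4 and 10.7% for MAP3K2. Among neurogenesis and neuron differentiation genes, 4 of 38 were lower in both and 1 was higher in both (percentiles 19.3 and 40.9). ELAVL4 was covered over 6.16% and POU3F3 over 4.30% in the control and 0% in both hairpins, and EBF1 over 8.96%, 15.7% and 11.3% in control, sh1 and sh4.

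For the other lists the percentiles of the mean difference are given for sh1 and then sh4. Neural progenitor markers were lower in both hairpins for 2 of 24 and higher in both for 2 (percentiles 21.6 and 13.6). FABP7, a radial glia marker, was covered over 21.8% and the RNA-binding gene MSI2 over 10.3% in the control, and 0% in both hairpins. The 2 that were higher were DACH1, with 0.652%, 2.56% and 2.80% in control, sh1 and sh4, and CDH2, with 0%, 5.49% and 1.72%. Axon guidance and synapse genes were lower in both for 11 of 30, higher in both for 3 and opposite in the hairpins for 9 (percentiles 63.8 and 20.8), among them the ephrin receptor gene EPHA4 with 14.8%, 0% and 1.79% and the netrin receptor gene UNC5C with 8.44%, 17.8% and 13.4%. Growth factor genes were lower in both for 7 of 29, higher in both for 0 and opposite for 8. Their mean difference in sh1 was -0.00215 percentage points against a random median of -1.75 (percentiles 94.6 and 59.9). Coverage was 13.1%, 7.06% and 1.87% in control, sh1 and sh4 at EGFR and 13.2%, 4.56% and 1.203% at IGF1R. Wnt, Notch and Hedgehog genes were lower in both for 7 of 34 and higher in both for 2 (percentiles 61.8 and 8.75), with 10.3% in the control and 0% in both hairpins at CTNNB1, the β-catenin gene. H3K36 enzymes and readers were lower in both for 4 of 21 and higher in both for 2 (percentiles 27.5 and 18.4). The DNA methyltransferase genes DNMT3A and DNMT3B were at 14.6% and 10.6% in the control and 0% in both hairpins, and ZMYND11 was at 0%, 3.69% and 3.85%. The KDM2A gene was at 0% in all 3 libraries.

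Polycomb genes were lower in both for 5 of 30, higher in both for 1 and opposite for 4. Their mean coverage was 2.51% in the control, 0.574% in sh1 and 2.78% in sh4 (percentiles 27.7 and 92.3), with 13.9%, 2.32% and 1.67% at JARID2 and 0%, 2.61% and 10.05% at PHC2. Neural crest genes were lower in both for 3 of 16 and higher for 0 (percentiles 9.93 and 19.4), with TFAP2B at 23.9% in the control and 0% in both hairpins. For astrocyte and oligodendrocyte genes the counts were 4 and 2 of 21 (percentiles 55.8 and 64.6), with the myelin gene MBP at 12.8% and then 0%. Pluripotency genes were lower for 1 and higher for 0 of 22 (percentiles 91.6 and 19.3), and mesoderm and endoderm genes for 2 and 0 of 30 (percentiles 89.0 and 54.0). Cell cycle genes were lower for 2 and higher for 1 of 34 (percentiles 49.1 and 21.5), where CDK6 was at 7.60%, 14.8% and 13.2% and CCND3 and RB1 were at 4.34% and 3.93% in the control and 0% in both hairpins. HOX and ribosomal protein genes were at 0% in all 3 libraries, and blood, liver and muscle genes were lower for 0 and higher for 1 of 30 (percentiles 41.6 and 86.4). Olfactory receptors were lower in both for 3 and higher in both for 0 of 389 (percentile 94.8 in sh1). In sh4, 17 of them were higher than the control and 3 lower, and the mean difference of 1.36 percentage points lay at percentile 99.7. Of these 17, 7 lie on chromosome 1 beyond 140 Mb. Without that part 10 were higher and 3 lower, and the mean difference was 1.04 percentage points (percentile 98.4). Neighbouring genes of this family can share 1 region, so they are not independent, while the random lists were not matched on position. For sh1, 0 of the 17 lists lay outside percentiles 2.5 to 97.5, and for sh4 the olfactory receptors were the 1 list that did. By measure, 4 of 17 lists lay outside percentiles 2.5 to 97.5 for all KDM2A peaks. The count was 0 for KDM2A peaks with an FDR under 0.05, 0 for sh1 and 1 for sh4. Chance would give 0.85 each only if every list could reach both tails. With the FDR limit, lists with 0 bound genes, the lowest value possible, lay at percentiles 8.27 to 19.6. HOX and ribosomal protein genes had no control coverage to lose and lay at percentiles 24.5 to 30.1 in the hairpins. The counts of 0 are therefore weak evidence that no list differed.

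Whether H3K36me2 differed where KDM2A binds was compared at gene ends. KDM2A-bound genes with H3K36me2 at an end numbered 981 in the control, 614 in sh1 (0.626 times, 0.566 to 0.692) and 636 in sh4 (0.648 times, 0.587 to 0.716), and unbound genes 193, 147 (0.762 times, 0.615 to 0.944) and 157 (0.813 times, 0.659 to 1.00). Among regions that passed the binomial test the bound genes numbered 57, 55 and 97, and the unbound genes 12, 19 and 25. Over all regions the ratio was lower at bound genes, but the bound and unbound intervals overlapped in each hairpin and their difference was not tested. Bound and unbound genes were not matched on gene density here. KDM2A peaks were denser in gene-rich windows, where both hairpins held fewer regions. The lower ratio at bound genes stayed with 1 kb and 5 kb windows, with equal numbers of regions and without chromosome 1 beyond 140 Mb. With KDM2A peaks of FDR under 0.05 this difference was absent, at 0.667 and 0.683 for bound and 0.647 and 0.675 for unbound genes. With the 10% of peaks of highest fold the ratios were 0.621 and 0.677 against 0.654 and 0.675. Above the control's median fold they were 0.884 and 0.871 against 0.755 and 0.939. Of 981 KDM2A-bound genes with H3K36me2 at an end in the control, 798 (81.3%, 78.8 to 83.7) had none there in either hairpin. Of 193 genes without KDM2A it was 150 (77.7%, 71.3 to 83.0). The difference of 3.63 percentage points (-2.73 to 9.98) was not detectable at this number of genes. The bound share of 81.3% lay at percentile 66.9 of random gene sets, whose median was 80.8%. Most genes with H3K36me2 at an end in the control were bound, so this percentile is a weak check. In the other direction, of 15673 bound genes with no H3K36me2 at an end in the control, 74 (0.472%) had it in both hairpins, and of 2970 unbound genes 18 (0.606%). That difference was -0.134 percentage points (-0.433 to 0.165), and it turned to 0.292 (-0.249 to 0.833) with KDM2A peaks of FDR under 0.05. For gains, unlike losses, no random genes matched on length were drawn. Taking sh1 as the reference, 71.7% of bound and 73.5% of unbound genes had none in the other libraries, and for sh4 72.0% and 71.3%. Among the genes with the highest KDM2A folds, AGMAT was covered over 31.5% in the control and 0% in both hairpins, NRIP3 over 23.4%, 9.19% and 0%, and ELMOD1 over 14.0%, 8.73% and 13.0%. CLPB was at 0% in the control, 5.64% in sh1 and 0% in sh4, and KHSRP, OR7G2, GCDH, TRIM58, PKM and HEBP2 were at 0% in all 3 libraries.

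KDM2A peaks with an FDR under 0.05 lay inside H3K36me2 regions less often than the covered share of the genome. It was 2.95% (2.69 to 3.23) in the control against 3.50%, a ratio of 0.843. The ratio was 0.856 in sh1 and 0.703 in sh4. For all KDM2A peaks the ratios were 1.18, 1.12 and 0.960, so the direction depended on the peak limit in the control and sh1.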

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

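All tests of explanations named here were chosen after the result was seen. The hairpins differed in their total against the control, with covered H3K36me2 length 0.926 times the control in sh1 and 1.102 times in sh4; the difference between hairpins was not tested. On chromosome 1 beyond 140 Mb the ratios were 0.839 in sh1 and 4.14 in sh4, also not tested. The KDM2A list held 362 peaks with an FDR under 0.05 on sequences outside chromosomes 1 to 22 and X, which the comparisons did not use.

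The excess of sh4 on chromosome 1 beyond 140 Mb, the greater part of the long arm, was weighed first. Input reads per kb in sh4 regions there were 1.26 times those of the rest of the genome, while the ratio was 1.00 in the control and 1.01 in sh1, and the 21 other parts of the sh4 genome with at least 50 regions lay between 0.955 and 1.01. Chromosomes 19 and 22 held only 6 and 13 sh4 regions, at 1.21 (0.862 to 1.92) and 1.04 (0.928 to 1.06), against 1.25 (1.23 to 1.26) for this arm on the same scale. A stronger mark alone would leave input as elsewhere, and the median fold there was not higher but differed from the rest by -0.128. Extra copies of this arm in some or all of the sh4 cells are a candidate explanation, and human stem cell lines are known to gain chromosome arms in culture.

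The low overlap of the 3 region lists was weighed next. If loss of control regions through the knockdown were the whole cause, sh1 and sh4 should share most of their length, but they shared 11.3% of sh1. Counting error near the calling limit stays open, since regions that passed the binomial test shared 2.33 percentage points more of their length with either other library than the remaining regions on average, but not in sh4 (21.2%, 22.5% and 16.2% in control, sh1 and sh4, against 16.3%, 19.4% and 17.3%). In simulated repeats 73.5% to 78.3% of all regions were called again at their listed excess. With the excess reduced by 50% it was 16.3% to 21.2%, against 12.7% to 17.6% found in another library. For passing regions it was 98.7% to 99.01% at their listed excess and 44.6% to 50.2% with it reduced. Both exceed the 16.2% to 22.5% of their length that was shared, a measure by length. For passing regions this argues against counting error as the whole cause, unless their excess was overstated by more than 50%. For the remaining regions counting error stays open. How far selection overstated the excess, and how much libraries vary beyond counting, cannot be told apart with 1 library per group.

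The shift from gene-rich to gene-poor sequence in both hairpins was the third pattern. A rise of H3K36me2 at genes that lost the demethylase would go the other way, so it was not tested as a source of this fall. A difference in input between gene-rich and gene-poor sequence was not seen within the called regions, at 1.01 times the control for sh1, but the lists hold no input outside them, so it cannot be told apart. GC-dependent recovery of DNA that differs between libraries was not tested, as no genome sequence was used here, and neither were indirect effects of the knockdown.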

How the results depend on the processing

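Leaving out chromosome 1 beyond 140 Mb, the FDR limit, the known starts, the binomial test, the fold limit for KDM2A-bound genes and all alternatives for gene-rich windows and for genes with any coverage were chosen after the result was seen. Over 25 results and 107 alternatives, 52 values stayed within the interval of the reported value, 48 moved beyond it, 3 lost an outer percentile and 4 turned direction with an interval that left out no difference. In all, 9 lay on the other side of no difference from the reported value. The cause was not tested unless a setting's own construction shows it. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. Matching on CpG content was not run, since no genome sequence was used here. Depth limits the fold of a typical region to 1.25 to 2.09 in the control, and no depth is known for KDM2A.

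The ratio for KDM2A at gene ends was 1.42 with 1 kb, 1.204 with 5 kb, 1.25 for the 10% of peaks with the highest fold, 1.23 at the ends of all annotated genes, 1.28 with the FDR limit and 1.48 at known starts. MAPK genes with a KDM2A peak differed from the random median by -5.41 points as reported, by 4.05 with the highest folds and by 2.70 with the FDR limit, so the sign turned. Neurogenesis genes differed by 13.2, but left the outer percentiles with 1 kb (13.2, percentile 95.4), the highest folds (5.26, 76.7) and the FDR limit (5.26).

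Covered length turned direction in sh1, to 1.24 with regions above the control's median fold and 1.49 with the binomial test. In sh4 it was 1.50 and 2.61 there, 1.01 with equal numbers of regions and 0.986 without chromosome 1 beyond 140 Mb.

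Gene-rich regions turned direction in sh4 with the binomial test, at 1.41, and were 0.914 in sh1. They were 0.780 in sh1 and 0.797 in sh4 above the control's median fold, and in sh4 0.572 with equal numbers and 0.601 without chromosome 1 beyond 140 Mb. Relative to gene-poor regions sh1 moved to 0.505 with the binomial test. Genes with any coverage were 0.961 and 0.938 above the control's median fold and 0.733 in sh4 with equal numbers.

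Length found alone in control, sh1 and sh4 was 74.2%, 70.4% and 74.8% when regions with 1 bp of overlap counted as shared, 88.7%, 87.0% and 88.7% with 50% reciprocal overlap, and 95.9%, 95.5% and 97.5% with the binomial test. In control and sh1 it was 82.4% and 79.0% when joined across 5 kb and 83.7% and 80.7% with equal numbers. In sh4 it was 82.9% without chromosome 1 beyond 140 Mb. The binomial test left only 7.96, 11.9 and 20.7 Mb covered in control, sh1 and sh4, so less length remained to be shared. The higher shares found alone under that test therefore do not show that stronger regions coincided less. Genes that gained H3K36me2 in both hairpins, bound minus unbound, were at -0.807 points with 5 kb and 0.292 with the FDR limit. KDM2A-bound genes with H3K36me2 at an end were 0.884 and 0.871 times the control in sh1 and sh4 above the control's median fold, 0.965 in sh1 with the binomial test and 0.585 in sh4 with equal numbers; in sh4 they turned direction with the binomial test, at 1.70. With 5 kb windows the share of length at gene ends over the genome's was 0.586 in the control, 0.417 in sh1 and 0.383 in sh4. The share of genes with any coverage differed from the control by -9.46 and -5.41 points for MAPK in sh1 and sh4. For neurogenesis it differed by -7.89 points in each. Among matched random lists the MAPK differences lay at percentiles 49.4 in sh1 and 90.0 in sh4. Those of neurogenesis lay at 10.4 and 13.0. These falls therefore lay within those of matched random lists.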

Other observations

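The tests and the choice of the sites named here were made after the values were seen. Ribosomal DNA stood out among the KDM2A peaks. The 3 annotated copies of the 45S precursor gene on chromosome 21 (RNA45SN1, RNA45SN2 and RNA45SN3) held 21 peaks with an FDR under 0.05 in 39.98 kb, or 525 per Mb against 5.32 per Mb over the genome. The highest pileup there was 188, in a peak at RNA45SN2 with a fold of 2.48. The highest fold was 5.24, at another peak of the same copy. Reads of repeated copies are placed on the few copies of the reference, and a matched input would share that excess, so the fold carries more than the pileup does. On the X chromosome, a peak at 115727125 to 115727443 had a fold of 16.75, the highest of the list. The transcript DANT2 nearby, of a repeat-rich locus, held 7 peaks with an FDR under 0.05 and folds up to 9.78, and 6 of these lie in DANT1, which DANT2 contains.

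KDM2A peaks with an FDR under 0.05 were also dense beside some centromeres and on the short arm of chromosome 21. The windows of 1 Mb with the highest numbers were 49 to 50 Mb of chromosome 5, with 66 peaks, 8 to 9 Mb of chromosome 21, with 58, and 53 to 54 Mb of chromosome 11, with 53. By gene density, such peaks numbered 5.41 per Mb in windows without a protein-coding gene, 4.56 with 1 to 4 genes, 5.16 with 5 to 9, 6.27 with 10 to 19 and 7.65 with 20 or more. All KDM2A peaks numbered 118, 160, 185, 207 and 228 per Mb in the same classes. The highest H3K36me2 folds lay on chromosome 17, with 2596.1 in sh1 at 25389801 to 25390000 and 2392 in sh4 at 24421401 to 24421600, and at copies of mitochondrial sequence on chromosome 1, with 756 in the control at MTCO1P12 and 1191 in sh1 and 973 in sh4 at MTATP6P1. The chromosome 17 regions were each 200 bp wide and lay at different positions in the hairpins. Only 18 regions in the control, 17 in sh1 and 17 in sh4 had a fold above 4. Whether such folds reflect the mark was not tested.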
